A study of Arabidopsis thaliana with 18 samples.

How the data were processed

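RNA of Arabidopsis thaliana plants was hybridised to one-colour Agilent arrays of a custom design, labelled with Cy3. The 18 arrays fall into 6 groups of 3, given by genotype and condition in the labels: the wild type Col-0, the mutant hda19 and the mutant hda5/14/15/18 (the quadruple mutant), each under non-stress conditions and 2 h after treatment with 125 mM NaCl. Per the labels, plants were treated 5 days after germination. The growth protocol in the labels names lines other than these genotypes, so no further growth conditions are given here. The labels call the samples biological replicates without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

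The deposited scanner files hold one array each. Per the file headers, they were made with Feature Extraction 10.7.3.1, and their processed signal is an intensity on a linear scale, after background subtraction, with no scaling between arrays. Per the file headers, the other columns used were the mean, median and background intensity of each spot and marks for control spots, outlier spots, saturation and signal well above background. The deposited value table of the series holds log2 values that the authors normalised, and the submitters' processing notes name RMA, limma and R 2.12.1. Setting each of its columns against the same array showed its scale: normexp background correction with an offset of 16 on the median signals, quantile normalisation and log2, without centring. Recomputed in this way, the values differed from the authors' by at most 5e-09, and the lowest correlation of a column with log2 of the processed signal of its array was 0.9763. The medians of the table's columns lay between 5.84 and 5.86, and none of its scale, centring and direction stays unknown. The deposited value table was used as an alternative only.

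Log2 of the processed signal minus the 75th percentile of the array was analysed. The percentile signal lay between 535.6 and 658.2, between 50.8% and 56.1% of probes per array were well above background, no spot was saturated (0), and 12 to 40 outlier spots per array were left out. The 1319 control spots were left out of the 75th percentile and of every test. Of 53459 probe spots on an array, 52586 carried different probes and spots of one probe were averaged, while 439 probes share their sequence with another. For each of the 32781 loci with a probe, the probe with the highest mean was taken, since 97 loci had 2 probes. Both probes of 95 loci passed the filter, and in no case (0) did they pass a test in opposite directions. A locus was tested if it was well above background on all 3 arrays of at least 1 group, which left 22169 loci. Of these, 22089 were found in the reference table (TAIR10.1), 9215 have a symbol and 12954 are named by their locus alone. The chromosome of a gene is given by its locus code (AT5G is chromosome 5), and no coordinates are given because no genome was used here.

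Linear models were fitted with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table for reading. One model held the 6 group means of all 18 arrays, which share 1 estimate of the spread. From it came 11 contrasts: salt against non-stress in each genotype, each mutant against Col-0 and against the other mutant in each condition, and the difference in salt response between each mutant and Col-0. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and a locus was called at adjusted p below 0.05. The number of called loci with at least a 2-fold change is given beside each count. Values are log2 fold changes ± SE from limma, with 3 arrays per group. Where a gene was not well above background on any array of a group, its change is given as at least N-fold. This bound sets the mean of the brighter group against the mean, over the arrays of the dim group, of the lowest signal well above background or of the gene's own signal, whichever was higher. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

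Before the data were examined, 22 lists of 349 genes were fixed, of which 331 genes were tested. They cover late embryogenesis abundant and cold-regulated proteins, other ABA-responsive genes, ABA receptors, kinases and transcription factors, clade A protein phosphatases 2C, ABA synthesis and breakdown, proline and raffinose metabolism, sodium and potassium transport, stress-regulated transcription factors, heat shock proteins and factors, jasmonate, salicylic acid, auxin, flavonoids, glucosinolates, iron deficiency, the circadian clock, the mitotic cell cycle, histone deacetylases, seed storage and the embryo programme, light harvesting and carbon fixation, root hair cells and root endodermis. Each list was tested in each contrast with camera of limma at a preset correlation of 0.01, and its p was adjusted over all 242 tests, of which 79 passed. Only 11 of these calls were kept with a correlation estimated from the residuals: other ABA-responsive genes in the salt responses of Col-0 and hda19, late embryogenesis abundant proteins in that of hda19, proline and raffinose metabolism and stress-regulated transcription factors in all 3 salt responses, and auxin response in the salt response of the quadruple mutant and in its difference from Col-0. For the other lists named, the adjusted p with an estimated correlation is given beside the call. The rule for named genes was also fixed. In each contrast these are the 8 highest and 8 lowest fold changes (6 and 6 between the mutants and for the differences in salt response) among called loci with a symbol, at least a 2-fold change and no overlap between the arrays of both groups, which was not asked of differences in salt response. Of each list they are up to 4 called members with the largest change, up to 2 members that did not pass and up to 2 further members called in the opposite direction. The 5 mutated genes are named throughout, and some genes were left out for length. All other genes are said to have been chosen after their values were seen.

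The arrays lie on 3 slides scanned on 2 days. Slide 1 held replicate 1 of all 6 groups (6 arrays), slide 2 held replicate 2 of all groups and replicate 3 of hda19 (8 arrays), and slide 3 held replicate 3 of Col-0 and of the quadruple mutant (4 arrays). The slide was tested as a block and within each slide. Looking on a slide at loci called without it was added after the data were seen. Whether equal replicate numbers pair arrays was checked by the correlation of deviations from group means. It was above 0.1 for every pair in the salt response of Col-0 (0.128 to 0.362). So it was for the quadruple mutant against Col-0 without (0.116 to 0.386) and with NaCl (0.188 to 0.376). There number and slide coincide and cannot be told apart. Other alternatives were quantile normalisation, normexp with an offset of 50 and quantile normalisation, the deposited value table, no filter, the mean of a locus's probes, array weights, a fit of only the groups compared, each array left out in turn and, for lists, fry. Leaving out chromosome 5 was also added then.

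Fits were tested on 22169 simulated loci with 200 changed. For the salt response in Col-0, 67.2%, 88.1% and 95.5% of loci changed 1.5-, 2- and 4-fold were recovered, and 4.02% of calls were false. For the difference in salt response of hda19 the shares were 55.2%, 74.6% and 92.4% with 3.9% false calls, and 55.2%, 74.6% and 89.4% with 2.67% for the quadruple mutant. A shifted list of 15 members was found by camera (adjusted p = 5.43e-31), with 0 of 21 unshifted lists called. This may not hold for correlated genes.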

Results

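Gene expression was measured on 18 one-colour Agilent arrays, 3 for each of 6 groups: Col-0, hda19 and the quadruple mutant hda5/14/15/18, each without stress and 2 h after 125 mM NaCl. Histone deacetylases remove acetyl groups from histone tails. HDA19 belongs to class I and HDA5, HDA14, HDA15 and HDA18 to class II of the RPD3-like family, and the series sets the salt responses of mutants in genes of either class side by side. Of 32781 loci with a probe, 22169 were well above background in at least 1 group and were tested. Correlations between replicate arrays of a group lay between 0.99 and 0.996, and no pair of arrays held identical signals (0 of 153). The first principal component held 56.2% of the variance and separated arrays with and without NaCl. The second, with 21.1%, set hda19 against the quadruple mutant, and the third, with 10.1%, set Col-0 against both mutants. The number of arrays, 3 per group, limits the precision.

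The mutated genes were examined first. HDA19 (AT4G38130) was well above background on all 6 Col-0 arrays (mean 3.05 ± 0.12 without NaCl and 2.82 ± 0.11 with NaCl, log2 relative to the 75th percentile, SD, n = 3) and on none of the 6 hda19 arrays. It was at least 306-fold lower in hda19 without NaCl (limma adjusted p = 1.41e-17) and at least 236-fold lower with NaCl (adjusted p = 2.17e-17). In the quadruple mutant HDA14 (AT4G33470) fell by 6.09 ± 0.12 without NaCl and fell by 6.04 ± 0.12 with NaCl on the log2 scale. HDA15 (AT3G18520) was at least 36.3- and 44.6-fold lower there, and HDA18 (AT5G61070) at least 4.23- and 2.86-fold lower (limma adjusted p = 5.73e-06 and 8.75e-05 for HDA18 and smaller for the others). HDA5 (AT5G61060) did not differ from Col-0 in the quadruple mutant by limma (log2 fold change 0.14, adjusted p = 0.488 without NaCl and 0.13, adjusted p = 0.456 with NaCl). Where its probe lies relative to the insertion is not known here, and a probe outside the disrupted part checks nothing. HDA18 was also higher in hda19 than in Col-0 (1.27 ± 0.33 without NaCl, adjusted p = 0.00816, and 1.29 ± 0.33 with NaCl, adjusted p = 0.00747).

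**Figure D1:**
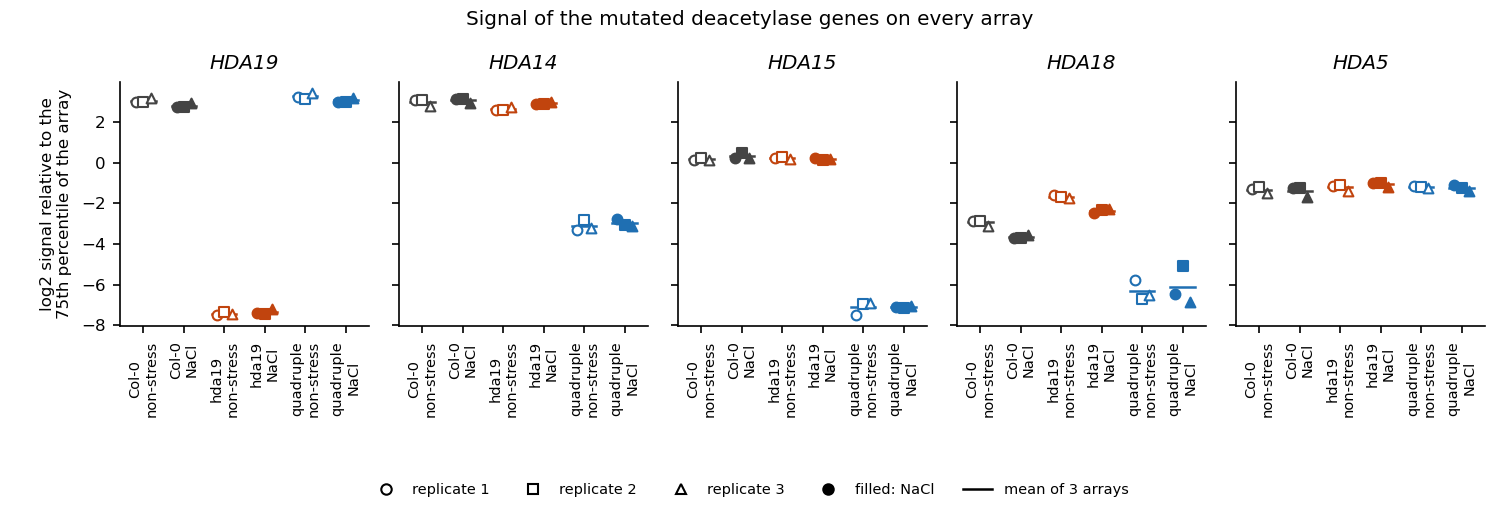
Log2 signal of HDA19, HDA14, HDA15, HDA18 and HDA5 relative to the 75th percentile of the array, for each of the 18 arrays (points, filled with NaCl) with the mean of each group of 3 (lines). HDA19 is low on all 6 hda19 arrays, HDA14, HDA15 and HDA18 are low on the 6 arrays of the quadruple mutant, and HDA5 is at a similar level in every group.

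The first comparison asked what 2 h of 125 mM NaCl changes in the wild type. In Col-0, genes of the response to abscisic acid (ABA), the hormone of water deficit, were among those that rose. LEA4-5 (AT5G06760), a late embryogenesis abundant protein of drying tissue, rose by 8.22 ± 0.27 and RD29B (AT5G52300), a standard ABA reporter gene, by 7.44 ± 0.26 on the log2 scale. HSFA6B (AT3G22830), a heat shock factor, rose by 7.74 ± 0.18 and CML37 (AT5G42380), a calmodulin-like protein, by 7.96 ± 0.44. The ABA-induced membrane protein TSPO (AT2G47770) was at least 250-fold higher, and the transcription factors RRTF1 (AT4G34410), BHLH92 (AT5G43650) and ORA47 (AT1G74930) were at least 149-, 105- and 169-fold higher, since none was well above background without NaCl. The ABA receptor gene PYL6 (AT2G40330) had the lowest log2 fold change of the named genes, -4.31 ± 0.33. The sterol desaturase CYP710A3 (-3.57 ± 0.48), the receptor-like kinase CRK30 (-3.19 ± 0.39), the transporter OCT3 (-2.99 ± 0.40) and the arabinogalactan protein FLA9 (-2.89 ± 0.19) also fell. The highest adjusted p of these genes was 1.69e-05 (limma, CYP710A3). Only 2 of 3 arrays were well above background for CML37 without and for CYP710A3 and OCT3 with NaCl.

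ABA-related lists rose in Col-0. Of 21 late embryogenesis abundant and cold-regulated genes, 19 rose (19 adjusted over the list alone), with a median of 4.41, or 3.13 with dim genes at their bound (camera adjusted p = 5.72e-16, adjusted p = 0.0539 with an estimated correlation). Other ABA-responsive genes rose in 14 of 16 (14 adjusted over the list alone, adjusted p = 4.03e-11), RD20 (6.12 ± 0.20) among them. All 9 clade A protein phosphatases 2C, negative regulators of ABA signalling, rose (9 adjusted over the list alone, adjusted p = 7.06e-09, adjusted p = 0.0731 with an estimated correlation), with HAI1 (1 of 3 unstressed arrays well above background) at 6.45 ± 0.50, HAI2 at 6.08 ± 0.26 and HAI3 at least 41.1-fold higher. In ABA synthesis and breakdown 10 of 13 genes rose (10 adjusted over the list alone, adjusted p = 5.82e-05, adjusted p = 0.0973 with an estimated correlation), including NCED3 (5.80 ± 0.15), the key enzyme of ABA synthesis, and the ABA hydroxylase CYP707A1 (3.1 ± 0.21). The list of ABA receptors, kinases and transcription factors went both ways, with 9 of 19 genes higher and 7 lower (16 adjusted over the list alone, adjusted p = 0.133). In it PYL7 (2.87 ± 0.15) and ABF3 (2.27 ± 0.08) rose, while PYL4 (-2.37 ± 0.24), PYR1 (-1.62 ± 0.07) and PYL1 (-1.28 ± 0.09) fell.

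Stress-regulated transcription factors rose in 23 of 24 genes in Col-0 (23 adjusted over the list alone, adjusted p = 1.48e-18), with the cold regulators CBF1 at 6.60 ± 0.38 and DREB1A (2 of 3 unstressed arrays well above background) at 5.66 ± 0.35. Of 23 jasmonate genes 19 rose and 1 fell (20 adjusted over the list alone, adjusted p = 6.57e-09, adjusted p = 0.208 with an estimated correlation). JAZ7 was at least 35.4-fold higher, ERF1 rose by 4.54 ± 0.36 and ORA59 fell by 1.45 ± 0.17. Of 15 salicylic acid genes 10 rose and 1 fell (11 adjusted over the list alone, adjusted p = 0.000927, adjusted p = 0.0612 with an estimated correlation), with PBS3 at least 24.7-fold higher and WRKY62 at 2.55 ± 0.38. Proline and raffinose metabolism rose in 9 of 14 genes and fell in 1 (10 adjusted over the list alone, adjusted p = 0.000687), led by the galactinol synthase GOLS2 (6.67 ± 0.44) and the proline synthesis enzyme P5CS1 (2.64 ± 0.15). Auxin response genes rose in 9 of 13 and fell in 1 (10 adjusted over the list alone, adjusted p = 0.000846, adjusted p = 0.108 with an estimated correlation), with LBD29 at 3.04 ± 0.25. Of 12 heat shock genes 7 rose (7 adjusted over the list alone, adjusted p = 0.00396, adjusted p = 0.392 with an estimated correlation). Of 14 flavonoid genes 6 rose and 1 fell (5 adjusted over the list alone, adjusted p = 0.0331, adjusted p = 0.707 with an estimated correlation), including the anthocyanin regulator PAP1 (2.48 ± 0.21). All 13 mitotic genes fell (13 adjusted over the list alone, median -0.57, adjusted p = 0.00157, adjusted p = 0.318 with an estimated correlation).

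The remaining lists did not pass as lists in Col-0. Of 18 sodium and potassium transport genes 7 rose and 5 fell (12 adjusted over the list alone, adjusted p = 0.335): the vacuolar exchanger gene NHX2 rose by 1.51 ± 0.07 and the potassium channel gene SKOR fell by 1.27 ± 0.22. Root hair genes fell in 10 of 12 and rose in 1 (11 adjusted over the list alone, adjusted p = 0.0514). Root endodermis genes fell in 6 of 11 and rose in 2 (9 adjusted over the list alone, adjusted p = 0.578). Light harvesting and carbon fixation genes fell in 3 of 22 and rose in 1 (2 adjusted over the list alone, adjusted p = 0.74). Glucosinolate genes fell in 9 of 13 and rose in 2 (11 adjusted over the list alone, adjusted p = 0.108). Clock genes rose in 5 of 13 and fell in 2 (7 adjusted over the list alone, adjusted p = 0.108). Iron deficiency genes rose in 3 of 9 and fell in 2 (5 adjusted over the list alone, adjusted p = 0.578). Histone deacetylase genes rose in 3 of 15 and fell in 6 (9 adjusted over the list alone, adjusted p = 0.456), among them HDT1 (-0.96 ± 0.06). No seed storage gene passed by limma (0 of 12, 0 adjusted over the list alone and 0 at an unadjusted p below 0.05, camera adjusted p = 0.651).

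In total 13569 loci passed in Col-0, of which 4823 were higher and 8746 lower with NaCl, and 3166 changed at least 2-fold (1975 higher and 1191 lower). With normexp 1834 changed at least 2-fold. With slide as a block 15059 loci passed. Of loci called without the arrays of a slide, 98.8% to 99.5% had the same direction on that slide. The median of all loci was -0.14 in Col-0, -0.08 in hda19 and -0.15 in the quadruple mutant, and -0.11, -0.12 and -0.12 with quantile normalisation. Every list shift that passed in a contrast of 2 groups kept its sign within each slide (174 of 174 values), and with slide as a block 72 of the 79 list calls were kept.

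The next comparison asked what NaCl changes in plants without HDA19. In hda19 LEA4-5 rose by 9.23 ± 0.27, the ubiquitin ligase PUB19 (AT1G60190) by 8.04 ± 0.16, GOLS2 by 7.80 ± 0.44 and HSFA6B by 7.69 ± 0.18 (1 and 2 of 3 unstressed arrays well above background). RRTF1, ORA47, CBF1 (AT4G25490) and BHLH92 were at least 205-, 161-, 147- and 90-fold higher. CRK30 fell by 4.73 ± 0.39, PYL6 by 4.69 ± 0.33 and PYL4 fell by 3.46 ± 0.24. WAK2, a wall-associated kinase, was at least 3.31-fold lower (adjusted p = 1.33e-06, the highest of these genes). All 21 late embryogenesis abundant and cold-regulated genes rose (21 adjusted over the list alone, median 4.22, or 3.62 with dim genes at their bound, adjusted p = 1.64e-17). So did 14 of 16 other ABA-responsive genes (14 adjusted over the list alone, adjusted p = 3.84e-11), RD20 among them (7.52 ± 0.20). Stress-regulated transcription factors rose in 23 of 24, with WRKY60 lower (24 adjusted over the list alone, adjusted p = 5.86e-17). Proline and raffinose genes rose in 10 of 14 and fell in 3 (13 adjusted over the list alone, adjusted p = 0.00105), with P5CS1 at 3.76 ± 0.15. All 9 phosphatases 2C (9 adjusted over the list alone, adjusted p = 7.06e-09) and 11 of 13 genes of ABA synthesis and breakdown (12 adjusted over the list alone, adjusted p = 0.000125) rose, with adjusted p = 0.0731 and 0.108 with an estimated correlation. Jasmonate genes rose in 21 of 23 (23 adjusted over the list alone, adjusted p = 3.74e-09), salicylic acid genes in 11 of 15 (12 adjusted over the list alone, adjusted p = 0.00425) and auxin genes in 10 of 13 (10 adjusted over the list alone, adjusted p = 0.000128). With an estimated correlation these lists had adjusted p = 0.198, 0.0872 and 0.0731.

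All 13 mitotic genes fell in hda19 with NaCl (13 adjusted over the list alone, adjusted p = 0.000192, adjusted p = 0.208 with an estimated correlation), CYCD3;1 by 0.87 ± 0.06. Root hair genes fell in 9 of 12 (10 adjusted over the list alone, adjusted p = 0.0347, adjusted p = 0.707 with an estimated correlation), a call that was lost with slide as a block (adjusted p = 0.0932) and without members on chromosome 5 (0.112, over all alternatives of the test 0.000473 to 0.707). Seed storage genes rose in 10 of 12 (10 adjusted over the list alone, adjusted p = 0.016, adjusted p = 0.707 with an estimated correlation), with cruciferin CRC at 4.18 ± 1.42 and SESA1 (1 of 3 unstressed arrays well above background) at 4.83 ± 1.53. These transcripts varied between the arrays of hda19. In total 12765 loci passed (5083 higher and 7682 lower) and 3013 changed at least 2-fold (2002 higher and 1011 lower), against 1766 with normexp. With slide as a block 14316 passed, and 98.3% and 98.7% of loci called without slides 1 and 2 had the same direction there.

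In the quadruple mutant, the same question was asked of plants mutated in class II genes. HSFA6B rose by 8.02 ± 0.18, LEA4-5 by 7.78 ± 0.27, CML37 by 7.59 ± 0.44, RD29B by 6.96 ± 0.26 and GOLS2 by 6.85 ± 0.44. TSPO, ORA47, RRTF1, BHLH92 and MAPKKK21 (AT4G36950) were at least 184-, 118-, 106-, 74.6- and 41.1-fold higher. PYL6 fell by 4.45 ± 0.33, CRK30 by 3.26 ± 0.39, FLA9 by 2.88 ± 0.19. The auxin-responsive genes SAUR75 and SAUR15 changed by -3.41 ± 0.36 and -2.82 ± 0.35 (adjusted p = 8.54e-06 for SAUR15, the highest of these genes). For HSFA6B and GOLS2 2 of 3 unstressed arrays were well above background. CML37, RD29B, BHLH92 and SAUR75 lie on chromosome 5 from AT5G25000 on. Late embryogenesis abundant and cold-regulated genes rose in 19 of 21 (19 adjusted over the list alone, median 3.33, or 2.87 with dim genes at their bound, adjusted p = 8.84e-14). Other ABA-responsive genes rose in 14 of 16 (14 adjusted over the list alone, adjusted p = 2.73e-10). With an estimated correlation these lists had adjusted p = 0.0683 and 0.0546. All 24 stress-regulated transcription factors rose (24 adjusted over the list alone, adjusted p = 1.42e-18), with DREB2A at 5.76 ± 0.27. Proline and raffinose genes rose in 9 of 14 and fell in 2 (12 adjusted over the list alone, adjusted p = 0.00149). Auxin response genes rose in 11 of 13 (11 adjusted over the list alone, median 2.06, adjusted p = 4.96e-07), with LBD29 at 4.84 ± 0.25 and LBD16, a regulator of lateral root formation, at 2.57 ± 0.11. All 9 phosphatases 2C rose (9 adjusted over the list alone, adjusted p = 7.11e-09, adjusted p = 0.0731 with an estimated correlation). So did 10 of 13 genes of ABA synthesis and breakdown (10 adjusted over the list alone, adjusted p = 3.41e-05, adjusted p = 0.0872 with an estimated correlation).

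Jasmonate genes rose in 18 of 23 and fell in 1 in the quadruple mutant with NaCl (20 adjusted over the list alone, adjusted p = 1.09e-07, adjusted p = 0.266 with an estimated correlation). Heat shock genes rose in 7 of 12 (7 adjusted over the list alone, adjusted p = 0.00137, adjusted p = 0.314 with an estimated correlation). Flavonoid genes rose in 6 of 14 (6 adjusted over the list alone, adjusted p = 0.0196, adjusted p = 0.702 with an estimated correlation). Mitotic genes fell in 11 of 13 (12 adjusted over the list alone, adjusted p = 0.0065, adjusted p = 0.42 with an estimated correlation). Salicylic acid genes rose in 9 of 15 and fell in 1 (11 adjusted over the list alone, adjusted p = 0.0192, adjusted p = 0.156 with an estimated correlation). Root hair genes fell in 9 of 12 and rose in 1 (10 adjusted over the list alone, adjusted p = 0.03, adjusted p = 0.702 with an estimated correlation). Without members on chromosome 5 these lists had adjusted p = 0.0963 and 0.128, and with slide as a block the root hair list had adjusted p = 0.0934, so that these calls were lost. Over all alternatives of the test the values ran from 1.2e-05 to 0.156 for salicylic acid and from 9.12e-05 to 0.702 for root hair genes. In total 13726 loci passed (4839 higher and 8887 lower) and 2933 changed at least 2-fold (1959 higher and 974 lower), against 1718 with normexp. The slide block gave 15276, and 98.6% to 99.1% of loci called without a slide had the same direction there.

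**Figure D2:**
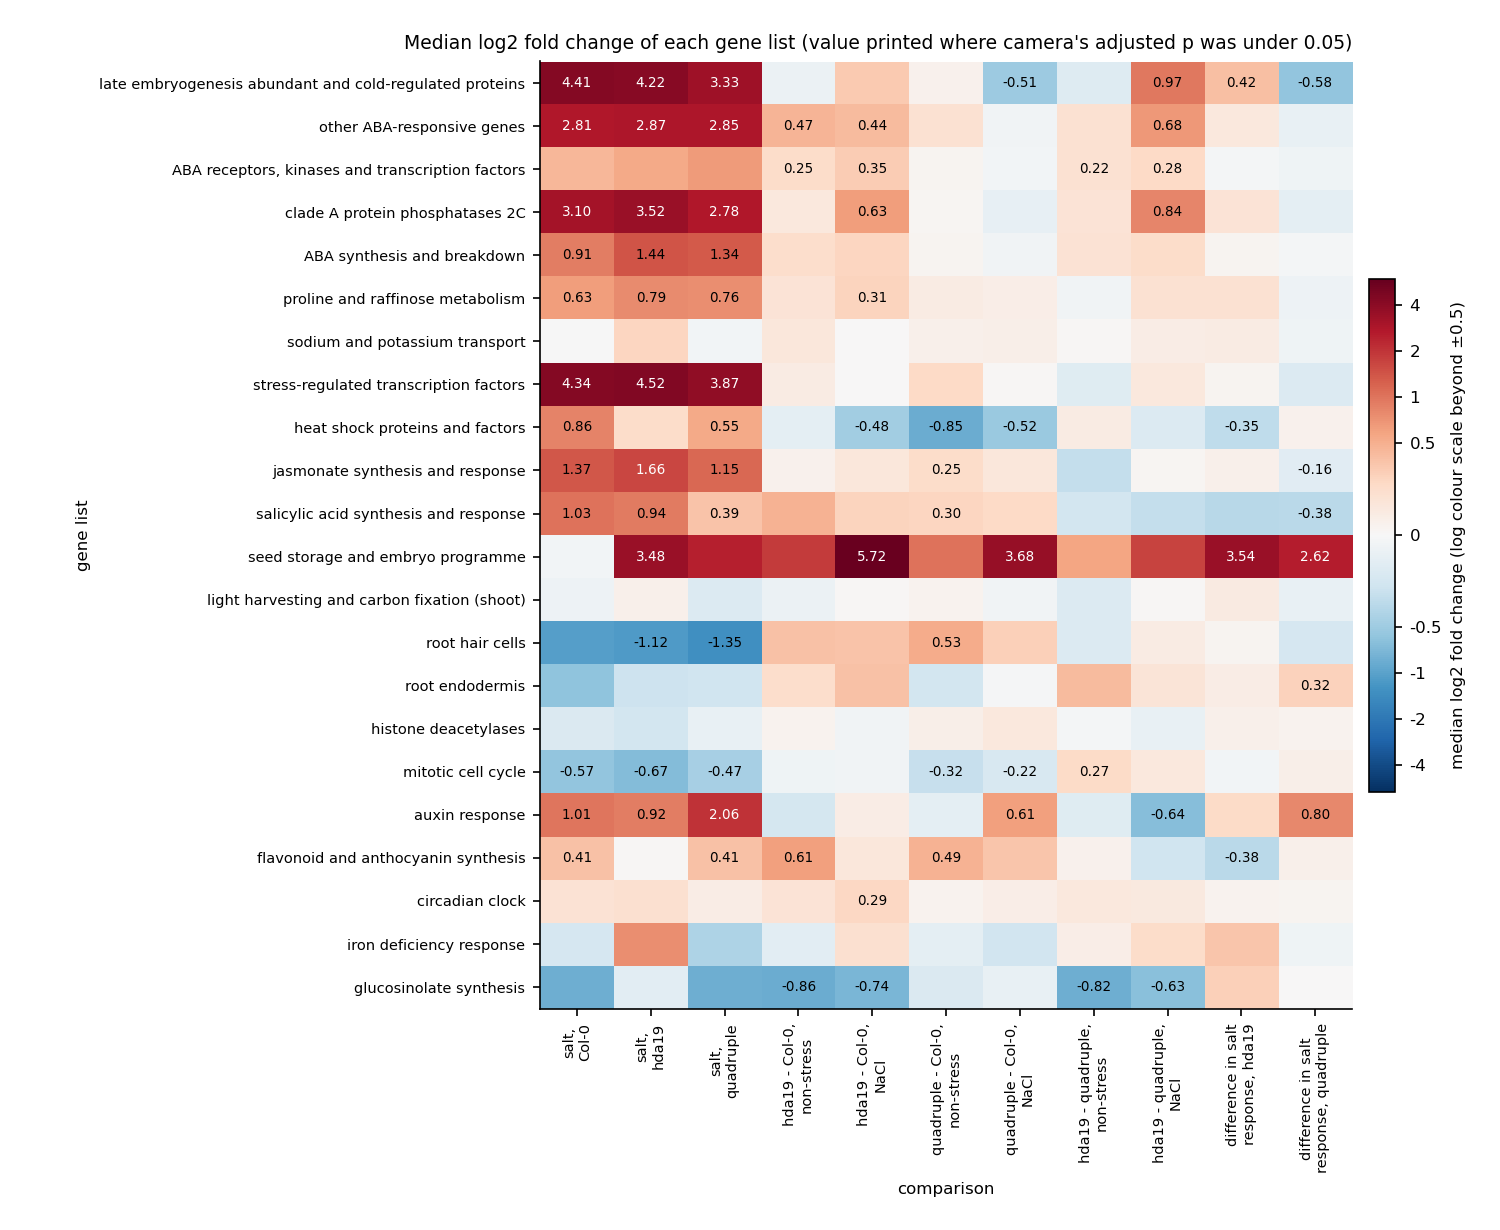
Median log2 fold change of each of the 22 gene lists (lines of the map) in each of the 11 contrasts (columns), with the value printed where camera's adjusted p was below 0.05. Lists of ABA-responsive genes and stress-regulated transcription factors are higher with NaCl in all 3 genotypes, with medians of 4.41, 4.22 and 3.33 for late embryogenesis abundant genes.

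The salt responses were then compared across loci. Over the 22169 loci, which are not independent replicates, log2 fold changes correlated with Pearson's r = 0.923 between Col-0 and hda19, 0.924 between Col-0 and the quadruple mutant and 0.886 between the mutants. At least a 2-fold change in any genotype was found for 4278 loci, of which 1933 changed at least 2-fold in the same direction in all 3 genotypes (1421 higher and 512 lower).

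Without NaCl, hda19 was compared with Col-0 to ask what the loss of HDA19 changes. Besides HDA19, the lowest values among loci with a symbol included MRD1 (AT1G53480, -7.32 ± 0.53, also low in the quadruple mutant). Of these, MAP1D (AT4G37040), a methionine aminopeptidase gene, and the defensin gene PDF1.5 (AT1G55010) were at least 32.8- and 16.6-fold lower. ALD1 (AT2G13810), an enzyme of pipecolic acid synthesis in plant defence, fell by 4.34 ± 0.39 and sks13 (AT3G13400) fell by 4.26 ± 0.34. The homeobox gene HDG3 (AT2G32370) was higher by 5.47 ± 0.60, FOLB3 (AT3G21730), of folate synthesis, by 4.65 ± 0.48, the senescence regulator NAP (AT1G69490) by 3.61 ± 0.36 and malate synthase MLS (AT5G03860), an enzyme of seed oil use, by 3.59 ± 0.36. ALD1 and sks13 were well above background on 1 of 3 hda19 arrays, and HDG3 and NAP on 1 of 3 Col-0 arrays. The ABA and seed regulator ABI4 (AT2G40220) was at least 3.88-fold higher (adjusted p = 0.000372, the highest of these genes) and ABI5 rose by 1.53 ± 0.13 (adjusted p = 1.01e-06). With these, 9 of 19 ABA receptors, kinases and transcription factors were higher (9 adjusted over the list alone, adjusted p = 0.0016, adjusted p = 0.0683 with an estimated correlation). Other ABA-responsive genes were higher in 9 of 16 and lower in 3 (13 adjusted over the list alone, adjusted p = 0.0347, adjusted p = 0.575 with an estimated correlation), with HIS1-3 at 1.16 ± 0.17 and RD20 at -1.25 ± 0.20. The call was lost without members on chromosome 5 (adjusted p = 0.112, over all alternatives of the test 0.00252 to 0.575).

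Glucosinolate synthesis, the source of mustard oils, fell in hda19 without NaCl: 9 of 13 genes were lower and 2 higher (13 adjusted over the list alone, median -0.86, adjusted p = 9.54e-05, adjusted p = 0.105 with an estimated correlation). CYP79F1 fell by 3.97 ± 0.27, its regulator MYB29 fell by 3.39 ± 0.39, CYP83A1 by 2.48 ± 0.15 and MAM1 by 2.07 ± 0.17, genes of the branch from methionine, while CYP83B1 of the branch from tryptophan was higher (0.37 ± 0.12). Flavonoid genes were higher in 8 of 14 (10 adjusted over the list alone, adjusted p = 0.00396, adjusted p = 0.589 with an estimated correlation), with the anthocyanin regulators PAP2 (AT1G66390) and PAP1 at 2.1 ± 0.21 and 1.82 ± 0.21. The salicylic acid list went both ways (6 of 15 higher and 3 lower, 10 adjusted over the list alone, adjusted p = 0.213), with PR1 at least 4.47-fold lower and PR5 (1 of 3 hda19 arrays well above background) at -2.88 ± 0.46. So did sodium and potassium transport (6 of 18 higher and 3 lower, 10 adjusted over the list alone, adjusted p = 0.52), in which SKOR (-2.43 ± 0.22), CAX3 (-1.94 ± 0.14) and the sodium transporter gene HKT1 (-1.64 ± 0.20) were lower. Iron deficiency genes were lower in 3 of 9 and higher in 1 (4 adjusted over the list alone, adjusted p = 0.625), among them the iron transporter gene IRT1 (-3.60 ± 1.18, adjusted p = 0.0288, 1 of 3 hda19 arrays well above background) and IMA1 (-2.12 ± 0.50, adjusted p = 0.00488). Of 12 seed storage genes 3 were higher and 1 lower (5 adjusted over the list alone, adjusted p = 0.104): SESA2 was at least 5.28-fold higher. The list median was 1.87, or 0.31 with dim genes at their bound, and these transcripts varied between the hda19 arrays. In total 7813 loci passed (3863 higher and 3950 lower) and 1232 changed at least 2-fold (571 higher and 661 lower). Quantile normalisation turned the balance (4028 higher and 3539 lower), and with normexp 434 changed at least 2-fold. The slide block gave 9280, and 98.4% and 98% of loci called without slides 1 and 2 had the same direction there.

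With NaCl, hda19 was compared with Col-0 to ask what differs under stress. Seed storage genes were higher in 11 of 12 (12 adjusted over the list alone, adjusted p = 0.00021, 0.575 with an estimated correlation). The median was 5.72, or 4.05 with dim genes at their bound. Of the 12, 8 passed the filter only on mutant arrays, which favours higher values. CRC (AT4G28520), well above background on 1 of 3 Col-0 arrays, was higher by 8.32 ± 1.42, SESA2 (AT4G27150) and SESA1 (AT4G27140) were at least 64.5- and 32.7-fold higher, and the oil body genes OLEO1 (AT4G25140) and OLEO2 (AT5G40420) at least 48.5- and 24.3-fold (adjusted p = 0.0058 for SESA1, the highest of these genes). LEC2, an embryo regulator, was lower but near background (-0.71 ± 0.20, adjusted p = 0.0118). The mean of the 11 storage genes ranged from -1.69 to 0.07 on these hda19 arrays. MAP1D was at least 32.4-fold lower, MRD1 fell by 5.04 ± 0.53, IRT1 by 5.00 ± 1.18 and AOP2, of glucosinolate synthesis, by 3.74 ± 0.37 (the last pair on 1 of 3 hda19 arrays well above background), while sks13 and PR1 were at least 8.93- and 4.01-fold lower. ABI3 was at least 3.48-fold higher and ABI5 was higher by 1.65 ± 0.13. Of 19 ABA receptors, kinases and transcription factors 11 were higher and 2 lower (16 adjusted over the list alone, adjusted p = 0.0226, adjusted p = 0.158 with an estimated correlation). Other ABA-responsive genes were higher in 8 of 16 and lower in 1 (9 adjusted over the list alone, adjusted p = 0.00931, adjusted p = 0.481 with an estimated correlation), with HIS1-3 at 2.09 ± 0.17. Phosphatases 2C were higher in 5 of 9 (5 adjusted over the list alone, adjusted p = 0.0347, adjusted p = 0.575 with an estimated correlation), with ABI2 at 1.11 ± 0.16. The call was lost without members on chromosome 5 (adjusted p = 0.141, over all alternatives of the test 0.00136 to 0.575).

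Proline and raffinose genes were higher in 6 of 14 in hda19 with NaCl (6 adjusted over the list alone, adjusted p = 0.0401, adjusted p = 0.156 with an estimated correlation), with P5CS1 at 1.15 ± 0.15. This call was lost with slide as a block (adjusted p = 0.063, over all alternatives of the test 2.9e-06 to 0.156). Late embryogenesis abundant and cold-regulated genes were higher in 11 of 21 and lower in 1 (12 adjusted over the list alone, adjusted p = 0.0598). Clock genes were higher in 5 of 13 (6 adjusted over the list alone, adjusted p = 0.0242, adjusted p = 0.492 with an estimated correlation). The call was lost without members on chromosome 5 (adjusted p = 0.0775, over all alternatives of the test 0.000739 to 0.492). Heat shock genes were lower in 7 of 12 (7 adjusted over the list alone, adjusted p = 0.0123, adjusted p = 0.481 with an estimated correlation). Glucosinolate genes were lower in 8 of 13 and higher in 1 (9 adjusted over the list alone, adjusted p = 0.000138, adjusted p = 0.108 with an estimated correlation), with CYP79F1 at -3.23 ± 0.27 and MYB29 at -2.11 ± 0.39. In total 7921 loci passed (4501 higher and 3420 lower) and 1104 changed at least 2-fold (555 higher and 549 lower). The balance turned with quantile normalisation (3809 higher and 4185 lower), and with normexp 498 changed at least 2-fold. Fitted on these groups alone 4734 loci passed, with slide as a block 9342, and 97.4% and 93.6% of loci called without slides 1 and 2 had the same direction there.

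**Figure D3:**
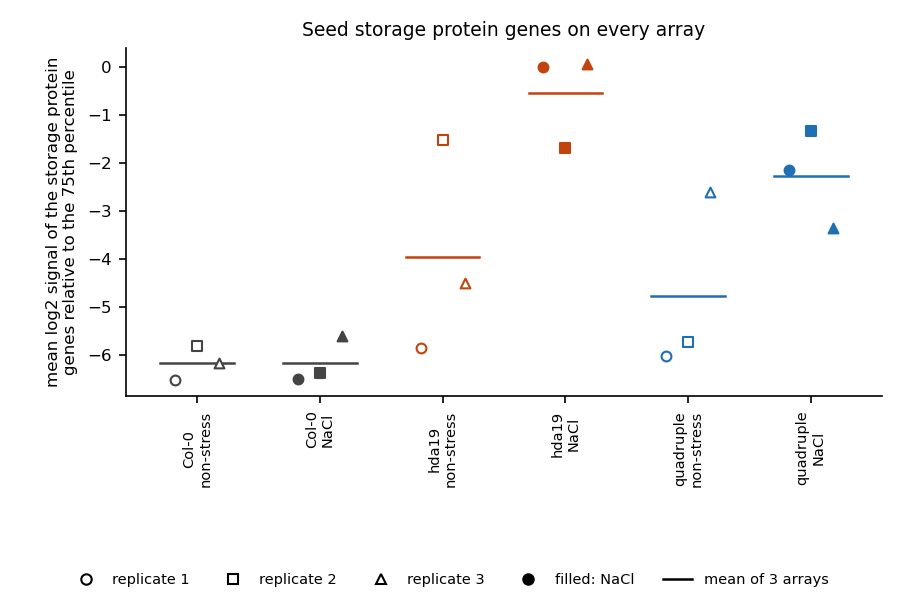
Mean log2 signal of the 11 seed storage genes relative to the 75th percentile of the array, for each of the 18 arrays (points, filled with NaCl) with the mean of each group of 3 (lines). Col-0 arrays lie between -6.52 and -5.61, and the hda19 arrays without NaCl at -5.86, -1.52 and -4.51.

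The quadruple mutant was compared with Col-0 without NaCl to find what differs. Besides the mutated genes, the lowest values among loci with a symbol belonged to ECS1 (AT1G31580, at least 819-fold lower) and UPF3 (AT1G33980, -6.51 ± 0.12) on chromosome 1 and to RANBP1 (AT5G58590), Hsp81.4 (AT5G56000), MAF3 (AT5G65060) and PLE (AT5G51600) on chromosome 5, at least 315-, 222-, 64.5- and 34.4-fold lower. Of 92 loci lowered at least 8-fold, 75 lay on chromosome 5 (81.5%, exact 95% interval 72.1% to 88.9%), which holds 23.1% of tested loci. From AT5G25000 on, 12% of chromosome 5 loci changed at least 2-fold, against 1.5% of those before it and 1.96% on chromosomes 1 to 4. In hda19 these shares were 5.65%, 4.99% and 5.61%. The strongest rises included SADHU1-3 (AT5G28626, 4.07 ± 0.08), a retroelement, ACP5 (AT5G27200, 3.38 ± 0.17) and PNG1 (AT5G49570, 2.92 ± 0.10) on the same part of chromosome 5. PCC1 (AT3G22231) and the defence genes PR2 (AT3G57260) and CRK6 (AT4G23140) were at least 6.64-, 3.87- and 4.29-fold higher (adjusted p = 0.00225 for CRK6, the highest of these genes).

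Salicylic acid genes rose in the quadruple mutant without NaCl in 6 of 15 (7 adjusted over the list alone, adjusted p = 0.00256, adjusted p = 0.0731 with an estimated correlation), with WRKY62 at 2.60 ± 0.38 and WRKY54 at 1.36 ± 0.14. Jasmonate genes rose in 8 of 23 (8 adjusted over the list alone, adjusted p = 0.00248, adjusted p = 0.575 with an estimated correlation), with CORI3 at 2.48 ± 0.18 and the defensin gene PDF1.2 (AT5G44420) at least 5-fold higher. Mitotic genes were lower in 9 of 13 (13 adjusted over the list alone, median -0.32, adjusted p = 1.59e-06, adjusted p = 0.105 with an estimated correlation), CYCB1;2 by -0.46 ± 0.08. Root hair genes were higher in 4 of 12 (8 adjusted over the list alone, adjusted p = 0.00396, adjusted p = 0.575 with an estimated correlation), such as the expansin gene EXPA7 (0.67 ± 0.20). Heat shock genes were lower in 4 of 12 (7 adjusted over the list alone, adjusted p = 0.016, adjusted p = 0.505 with an estimated correlation), with HSP18.2 (AT5G59720) at -1.54 ± 0.12 and HSP90.1 (AT5G52640) at -0.81 ± 0.16 on chromosome 5. Flavonoid genes were higher in 3 of 14 (5 adjusted over the list alone, adjusted p = 0.0238, adjusted p = 0.707 with an estimated correlation), a call lost with slide as a block (adjusted p = 0.0814, over all alternatives of the test 0.0257 to 0.707). Without members on chromosome 5 the calls of salicylic acid (adjusted p = 0.07), heat shock (0.723) and flavonoid genes (0.0519) were lost, with ranges over all alternatives of 5.92e-06 to 0.0731 and 0.00546 to 0.723 for the former lists. No root endodermis gene passed by limma (0 of 11, with 3 at an unadjusted p below 0.05), but the list, with adjusted p = 0.0614 by camera, passed with the replicate number as a block (0.0378, over all alternatives of the test 0.0378 to 0.707). In total 4047 loci passed (2136 higher and 1911 lower) and 734 changed at least 2-fold (303 higher and 431 lower). Quantile normalisation turned the balance (1828 higher and 1917 lower), and with normexp 294 changed at least 2-fold. Array weights gave 6752 loci, leaving out chromosome 5 gave 2414, slide as a block gave 5873, and 97.6% to 98.5% of loci called without a slide had the same direction there.

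**Figure D4:**
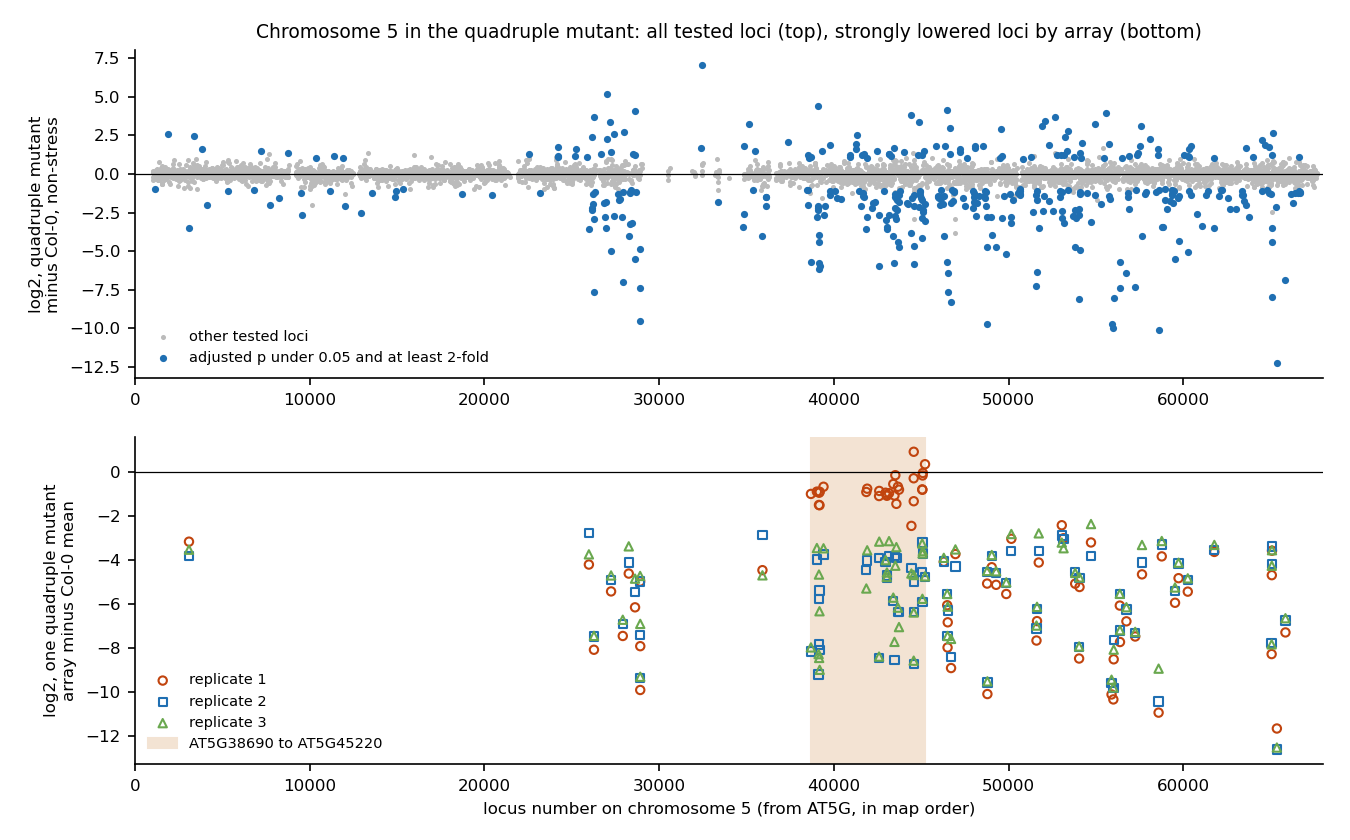
Log2 fold change between the quadruple mutant and Col-0 without NaCl (vertical axes) of chromosome 5 loci by the number in their locus code (horizontal axis), for all tested loci (top, blue where at least 2-fold and passing) and for each array of the mutant at the loci lowered at least 8-fold (bottom, 1 symbol per replicate). From AT5G25000 on 12% of loci changed at least 2-fold, and replicate 1 lies closer to Col-0 in the shaded stretch from AT5G38690 to AT5G45220.

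With NaCl, the quadruple mutant was compared with Col-0 to ask what differs under stress. Late embryogenesis abundant and cold-regulated genes were lower in 9 of 21 (9 adjusted over the list alone, median -0.51, adjusted p = 0.000191, adjusted p = 0.392 with an estimated correlation). The dehydrin gene RAB18 (AT5G66400) fell by 2.59 ± 0.43, RD29A (AT5G52310) by 1.32 ± 0.19, COR15B by 1.05 ± 0.26 and COR15A by 0.94 ± 0.29. Auxin response genes were higher in 6 of 13 and lower in 1 (9 adjusted over the list alone, adjusted p = 0.0143, adjusted p = 0.269 with an estimated correlation), with LBD29 at 2.02 ± 0.25 and LBD16 at 1.11 ± 0.11. Seed storage genes were higher in 11 of 12 (11 adjusted over the list alone, adjusted p = 0.00149, 0.607 with an estimated correlation). The median was 3.68, or 2.02 with dim genes at their bound, and again 8 passed the filter only on mutant arrays. CRC (1 of 3 Col-0 arrays well above background) was higher by 6.18 ± 1.42 and SESA2 at least 18.9-fold, and the storage mean ranged from -3.35 to -1.34 on these arrays. Mitotic genes were lower in 4 of 13 (4 adjusted over the list alone, adjusted p = 0.0025, adjusted p = 0.353 with an estimated correlation), with CDKB1;1 at -0.32 ± 0.06. Heat shock genes were lower in 7 of 12 (8 adjusted over the list alone, adjusted p = 0.0328, adjusted p = 0.575 with an estimated correlation). The call was lost without members on chromosome 5 (adjusted p = 0.594, over all alternatives of the test 0.00892 to 0.594). HAI1 (AT5G59220), a phosphatase 2C, was lower (-2.32 ± 0.50), as was the ABA receptor gene PYL1 (AT5G46790, -1.11 ± 0.09). RAB18, RD29A, HAI1 and PYL1 lie on the part of chromosome 5 from AT5G25000 on.

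ECS1 was at least 921-fold lower in the quadruple mutant with NaCl, and SADHU1-3 was higher by 4.60 ± 0.08. RANBP1, Hsp81.4, GER2 (AT5G39190), the resistance gene RPP8 (AT5G43470), MAF3 and PP2-A8 (AT5G45070) were at least 277-, 186-, 123-, 99.5-, 76.7- and 43.3-fold lower. The highest adjusted p of these genes was 0.000581 (GER2). GER2, RPP8 and PP2-A8 lie between AT5G38690 and AT5G45220, where replicate 1 of the mutant without NaCl stood apart. Of 104 loci lowered at least 8-fold with NaCl, 92 lay on chromosome 5 (88.5%, exact 95% interval 80.7% to 93.9%). In total 6035 loci passed (3257 higher and 2778 lower) and 949 changed at least 2-fold (412 higher and 537 lower), against 459 with normexp. Leaving out chromosome 5 gave 4012 loci, slide as a block gave 7996, and 96.1% to 98.8% of loci called without a slide had the same direction there.

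Both mutants share the Col-0 arrays as controls. Without NaCl 842 loci passed as higher in both mutants and 518 as lower, and 616 passed in opposite directions. Independent lists would share 372 and 340 loci. Simulated unchanged groups against the same controls shared 0 loci by limma in both conditions, which leaves out the effects and is no reference here. The covariance of the fold changes was 0.055 against a simulated 0.0165, and their correlation was 0.172 against 0.502 in simulations without effects. With NaCl 1021 loci were higher and 675 lower in both mutants and 1009 opposite, against 661 and 429 for independent lists. For the overlap of the mutant effects, NaCl, the count in the same direction was 1696, and 852 when only the groups compared were fitted. With NaCl the covariance was 0.0705 against a simulated 0.0164, and the correlation 0.2 against 0.5. The 3 control arrays cannot be split, so part of the excess over independent lists may come from the shared controls.

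The mutants were also compared directly. Without NaCl ECS1, RANBP1, Hsp81.4 and MAF3 were at least 479-, 329-, 242- and 64.8-fold higher in hda19 than in the quadruple mutant. MAP1D was at least 38-fold lower, SADHU1-3 was lower by -5.13 ± 0.08 and SDC (AT2G17690), a gene kept silent by DNA methylation in the wild type, by -4.90 ± 0.26. ABA receptors, kinases and transcription factors were higher in 10 of 19 and lower in 1 (11 adjusted over the list alone, adjusted p = 0.00326, adjusted p = 0.0731 with an estimated correlation). Mitotic genes were higher in 10 of 13 (10 adjusted over the list alone, adjusted p = 0.00105, adjusted p = 0.291 with an estimated correlation). Glucosinolate genes were lower in 8 of 13 and higher in 2 (10 adjusted over the list alone, adjusted p = 0.00433, adjusted p = 0.266 with an estimated correlation). In total 9192 loci passed (4212 higher and 4980 lower in hda19) and 1674 changed at least 2-fold (869 and 805). The slide block gave 10603, and 98.1% of loci called without slide 1 or 2 had the same direction there. Quantile normalisation turned the balance (4447 higher and 4175 lower), and with normexp 688 changed at least 2-fold.

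With NaCl, late embryogenesis abundant and cold-regulated genes were higher in hda19 than in the quadruple mutant in 14 of 21 (14 adjusted over the list alone, median 0.97, adjusted p = 0.000142, adjusted p = 0.392 with an estimated correlation), with RAB18 at 2.29 ± 0.43 and COR15B at 1.83 ± 0.26. Other ABA-responsive genes were higher in 10 of 16 (10 adjusted over the list alone, adjusted p = 0.00743, adjusted p = 0.459 with an estimated correlation), with HIS1-3 at 2.25 ± 0.17. The ABA receptor list was higher in 10 of 19 and lower in 2 (13 adjusted over the list alone, adjusted p = 0.0233, adjusted p = 0.158 with an estimated correlation), with ABI5 at 2.15 ± 0.13. Phosphatases 2C were higher in 7 of 9 (7 adjusted over the list alone, adjusted p = 0.0123, adjusted p = 0.519 with an estimated correlation), with HAI1 at 2.76 ± 0.50. RAB18 and HAI1 lie on chromosome 5 from AT5G25000 on. The call of phosphatases 2C was lost without members on chromosome 5 (adjusted p = 0.0865, over all alternatives of the test 0.000214 to 0.519). Glucosinolate genes were lower in 9 of 13 and higher in 1 (10 adjusted over the list alone, adjusted p = 0.00197, adjusted p = 0.208 with an estimated correlation). Auxin genes were lower in 5 of 13 and higher in 1 (6 adjusted over the list alone, adjusted p = 0.0447, adjusted p = 0.404 with an estimated correlation), with LBD29 at -3.58 ± 0.25 and LBD16 at -1.58 ± 0.11. This call was lost with slide as a block (adjusted p = 0.0639, over all alternatives of the test 1.47e-05 to 0.404). In total 10381 loci passed (5338 higher and 5043 lower in hda19) and 1784 changed at least 2-fold (947 and 837). The slide block gave 11801, and 97.8% and 97.2% of loci called without slides 1 and 2 had the same direction there. The balance turned with quantile normalisation (4861 higher and 5677 lower), and with normexp 842 changed at least 2-fold.

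The difference in salt response between hda19 and Col-0 was tested as an interaction, which alone tests the response. The difference in log2 fold change was 1.4 ± 0.28 for RD20 (adjusted p = 0.0217), 1.12 ± 0.21 for P5CS1 (adjusted p = 0.0177), 1.74 ± 0.29 for the galactinol synthase GOLS3 (adjusted p = 0.0104), 0.97 ± 0.18 for ERD7 (adjusted p = 0.0187) and 0.85 ± 0.19 for ERD10 (adjusted p = 0.0331). The lists of other ABA-responsive genes (1 of 16 higher, adjusted p = 0.309), ABA receptors, kinases and transcription factors (0 of 19 by limma, 0.521) and phosphatases 2C (1 of 9 higher, 0.367) did not pass. Among late embryogenesis abundant and cold-regulated genes 5 of 21 passed singly, all with a higher response (8 adjusted over the list alone, median 0.42, adjusted p = 0.00596, adjusted p = 0.575 with an estimated correlation). CIPK13 (-2.44 ± 0.35, adjusted p = 0.00549) and RTFL13 (-2.06 ± 0.28, adjusted p = 0.00368) had lower responses, as had PAP1 (-1.36 ± 0.30). These were higher in unstressed hda19. RD20 was lower, but not with NaCl (Col-0 4.03, hda19 4.18). Flavonoid genes shifted down with 1 of 14 passing (3 adjusted over the list alone, median -0.38, adjusted p = 0.000556, adjusted p = 0.541 with an estimated correlation). Heat shock genes shifted down with 1 of 12 (2 adjusted over the list alone, median -0.35, adjusted p = 0.000491, adjusted p = 0.258 with an estimated correlation). The seed storage list passed by camera, although no member passed singly by limma (0 of 12, with 6 at an unadjusted p below 0.05 and 1 adjusted over the list alone), with adjusted p = 8e-04 and adjusted p = 0.578 with an estimated correlation. As 8 of 12 members were not well above background in either Col-0 group, the size of this difference was not measured.

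In total 455 loci passed for hda19, 234 with a higher and 221 with a lower response, and 132 changed at least 2-fold (72 and 60). With quantile normalisation 37% of 460 loci were higher, against 51.4% of the 455. With slide as a block 883 passed. Without slides 1 and 2 only 6 and 2 loci passed, of which 4 and 2 had the same direction on the slide left out. On these slides list medians were 0.37 and 0.28 for late embryogenesis abundant, -0.79 and -0.44 for heat shock, 6.31 and 2.53 (not exact) for seed storage and -0.61 and -0.47 for flavonoid genes. The lists passed with slide as a block (adjusted p = 0.0217, 0.00123, 0.00764 and 0.00224). The count was 246 and 961 without hda19 NaCl replicates 1 and 2, 277 and 222 without hda19 non-stress replicates 2 and 3. It was 197, 195 and 262 without Col-0 non-stress replicates 1, 2 and 3, and 260 and 288 without Col-0 NaCl replicates 1 and 3. On the fourth principal component hda19 NaCl replicate 2 (3.6) stood apart from the others of its group (22.2 and 27.2), and its array weight was 0.433.

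The same interaction was tested for the quadruple mutant. Auxin response genes had a higher salt response than in Col-0, with 4 of 13 passing singly (6 adjusted over the list alone, median 0.80, adjusted p = 2e-07). The difference was 1.80 ± 0.36 for LBD29 (adjusted p = 0.0248), 1.37 ± 0.15 for LBD16 (adjusted p = 0.000505), 2.17 ± 0.43 for IAA29 (adjusted p = 0.0254) and 0.81 ± 0.15 for IAA1 (adjusted p = 0.0152), which was lower with NaCl in Col-0 (-0.33). This list call was kept with an estimated correlation. Late embryogenesis abundant and cold-regulated genes had a lower response, with 2 of 21 passing singly (9 adjusted over the list alone, median -0.58, adjusted p = 5.28e-09, adjusted p = 0.128 with an estimated correlation). LTI30 was at -0.65 ± 0.14 and RD29A at -1.22 ± 0.27, a gene not well above background without NaCl. The cytokinin response gene RR3 had a higher response (1.97 ± 0.27). TET15 (AT5G57810, -3.53 ± 0.28), PBS3 (AT5G13320, -3.86 ± 0.67, not well above background in unstressed Col-0) and GAT1_2.1 (-2.04 ± 0.34) had lower responses. Jasmonate genes shifted down with 1 of 23 passing (2 adjusted over the list alone, median -0.16, adjusted p = 0.0487, adjusted p = 0.709 with an estimated correlation, 0.0705 with slide as a block, and 0.0125 to 0.709 over all alternatives). Salicylic acid genes shifted down with 1 of 15 lower and 1 higher (7 adjusted over the list alone, median -0.38, adjusted p = 0.0323, adjusted p = 0.198 with an estimated correlation, 0.0576 with slide as a block, and 0.0114 to 0.491 over all alternatives). Root endodermis genes shifted up with 1 of 11 passing (2 adjusted over the list alone, median 0.32, adjusted p = 0.0116, adjusted p = 0.575 with an estimated correlation, and 0.00493 to 0.575 over all alternatives). Seed storage genes, of which 8 of 12 were not well above background in either Col-0 group, passed as a list with no member passing by limma (0 of 12, with 2 at an unadjusted p below 0.05 and 0 adjusted over the list alone), with adjusted p = 0.00779 by camera and adjusted p = 0.702 with an estimated correlation.

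In total 277 loci passed for the quadruple mutant, 187 with a higher and 90 with a lower response, and 134 changed at least 2-fold (90 and 44). Of these 277, 97 lie on chromosome 5 (35%), and leaving that chromosome out gave 139 loci. Without its members, salicylic acid (adjusted p = 0.491) and endodermis genes (0.26) lost their calls. With slide as a block 516 loci passed. Without slides 1, 2 and 3 there were 18, 37 and 91, of which 17, 32 and 86 had the same direction on the slide left out. Within slides 1, 2 and 3 the medians were 0.77, 0.98 and 0.65 for auxin, -0.89, -0.59 and -0.35 for late embryogenesis abundant, -0.34, -0.13 and -0.17 for jasmonate and -0.47, -0.23 and -0.53 for salicylic acid genes. Seed storage had the opposite sign on slide 3 (3.96, 4.94 and -1.01, not exact) and endodermis on slide 2 (0.72, -0.12 and 0.31). The count was 168 and 150 without non-stress replicates 1 and 3 of that mutant and 173 and 159 without its NaCl replicates 1 and 2. It was 153, 164 and 180 without Col-0 non-stress replicates 1, 2 and 3, and 159 without Col-0 NaCl replicate 1.

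**Figure D5:**
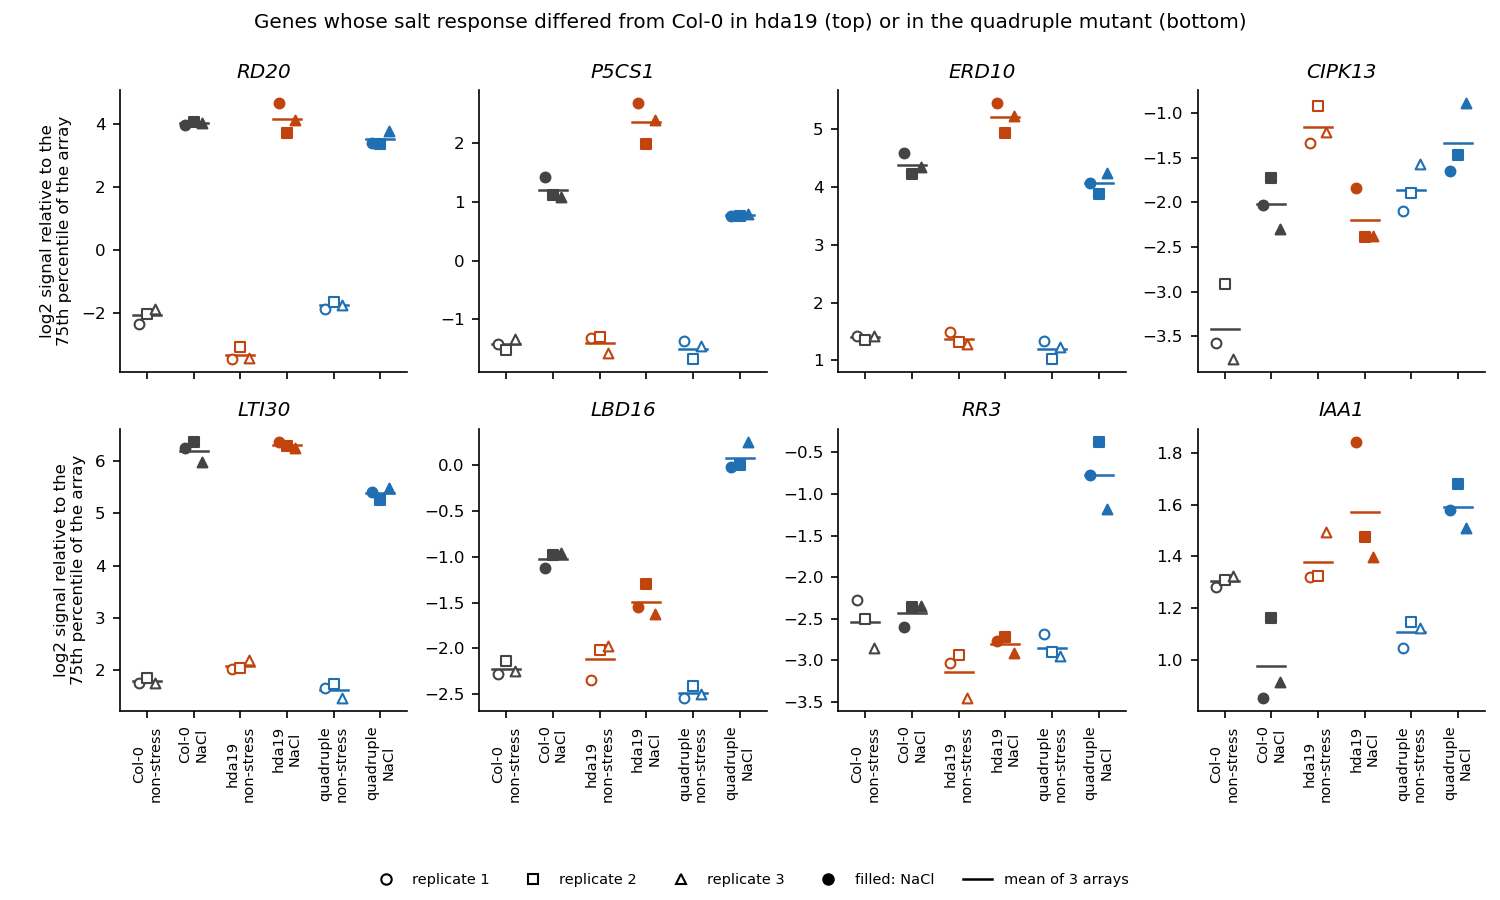
Log2 signal relative to the 75th percentile of the array for genes whose salt response differed in a mutant, on the 18 arrays (points, filled with NaCl) with the mean of each group of 3 (lines). RD20, lower without NaCl, and P5CS1 rise further in hda19 than in Col-0 (by 1.4 and 1.12), and LBD16 in the quadruple mutant (1.37).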

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

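The 9 tests of the 3 patterns weighed here were chosen only after the result was seen, while the tests with other splits of the arrays were written before. Groups of 3 arrays are too small for a test of the gap to the nearest sample. Array weights ranged from 0.374 (quadruple mutant NaCl replicate 3) to 2.89 (replicate 1 of that group).

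Strongly lowered loci of the quadruple mutant lay mostly on chromosome 5, and several loci with a different salt response lie there too. Of the 92 loci lowered at least 8-fold without NaCl, 75 (81.5%) were on this chromosome against 23.1% of tested loci. This argues against regulation of genes wherever they lie as the whole cause. Of the chromosome 5 loci so lowered in a fit without a slide, at least 97.7% were lower on that slide, which argues against a difference between slides. The share of loci changed at least 2-fold was 12% from AT5G25000 on, 1.5% before it and 1.96% on chromosomes 1 to 4. Any cause confined to that segment would give the ratio of the last pair, 0.765. AT1G31310, AT1G31430, ECS1, AT1G33102 and UPF3 on chromosome 1 fell strongly too, and a second segment was not tested. A candidate explanation is a strain variant in sequence or gene content carried along with a mutation. Altered expression within the segment remains open, untested without a genome sequence of the mutant.

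Replicate 1 of the quadruple mutant without NaCl stood apart at some of these loci. Between AT5G38690 and AT5G45220, 31 loci were strongly lowered on the other arrays of the mutant, and at 30 of them this array was within 2 log2 units of Col-0, with a median of -0.91 (53.4% of the Col-0 level) against -4.84 in replicates 2 and 3. Of all 92 loci strongly lowered on those other arrays 23.9% were within 1 log2 unit of Col-0 on this one, which argues against a mislabelled Col-0 array, as does HDA14 (-6.28 against Col-0). The median of the 10 such loci on chromosomes 1 to 4 differed from that inside by -4.377, which argues against wild-type RNA mixed into the sample. Of the strongly lowered loci between the outermost restored ones, 96.8% were restored, so the data are consistent with a segment still segregating in the seed stock. That remains a hypothesis found and tested on the same arrays, and a biological difference between the plants was not tested.

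Seed storage mRNAs differed between arrays of one mutant group. The mean of 11 storage protein genes was -5.86, -1.52 and -4.51 in replicates 1, 2 and 3 of unstressed hda19 and -6.02, -5.72 and -2.59 in the unstressed quadruple mutant, against -6.52 to -5.61 over the Col-0 arrays. Arrays of one group on one slide differed by up to 2.991, which argues against a difference between slides. RNA of dry mature seeds may be present. EM1 and EM6 varied by 0.677 over the 6 unstressed mutant arrays but were too dim to exclude it (well above background on 0). Expression of the embryo programme in mutant seedlings stays open. Of 5 measured pairs of regulator and contrast 1 was higher than in Col-0, ABI3 in hda19 with NaCl (at least 3.48-fold). LEC2, near background, was lower in hda19 (-0.69 and -0.71).

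A test of the difference in salt response called 455 loci for hda19. Of 100 splits that exchanged genotype labels within each condition, 9 gave as many loci, the real one included, and the highest of the others called 10959. Of the 9, 8 were among the 48 splits that exchange most labels in one condition, which turns the genotype effect itself (7813 and 7921 loci) into a difference in response, so plain splits do not decide about chance. With genotype and condition effects removed first, 1 of 100 splits gave as many (the real one) and the highest other gave 3. By unadjusted p, others gave up to 3531 loci against the real 3404, so chance stays open. For the quadruple mutant, with 277 loci, 11 of 100 plain splits gave as many, 9 of them of that kind, and the highest other gave 7961, which again does not decide. With both effects removed first, 2 of 100 gave as many, and the other one called 1369 loci. That split follows the slides, parting slide 2 from slide 3 in opposite ways, and with slide as a block 516 loci were called for the real grouping.

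The same test called gene lists by camera and genes by limma. In hda19 list medians of the difference were 0.42 for late embryogenesis abundant and cold-regulated genes, -0.35 for heat shock, 3.54 (not exact) for seed storage and -0.38 for flavonoid genes. The difference was positive for MYB108 (2.41), CYP76C2 (2.26), IAA5 (2.04), CYP71A20 (1.91), GOLS3 (1.74), IPS1 (1.71), RD20 (1.4), P5CS1 (1.12), CAX3 (1.1), ERD7 (0.97), COR413IM1 (0.97), ERD10 (0.85), PP2CA (0.77), LEA5 (0.56) and JAZ12 (0.36). It was negative for ASN1 (-2.46), CIPK13 (-2.44), RTFL13 (-2.06), ATSDI1 (-1.83), ESR1 (-1.80), MYB305 (-1.63), PAP1 (-1.36), HSP18.2 (-0.74) and NHX2 (-0.46). CYP71A20 and IPS1 were well above background on no hda19 array, so no response was measured. MYB108 and CYP76C2 were well above it on 1 of 3 unstressed ones.

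In the quadruple mutant the list medians were -0.58 for late embryogenesis abundant and cold-regulated genes, -0.16 for jasmonate, -0.38 for salicylic acid, 2.62 for seed storage, 0.32 for root endodermis and 0.80 for auxin genes. Higher responses were those of ACS9 (2.31), RTL1 (2.21), IAA29 (2.17), RR3 (1.97), LECRKA4.2 (1.96), WAKL5 (1.91), LBD29 (1.80), LBD16 (1.37), FMO1 (1.23), IAA1 (0.81), MYB36 (0.73) and PYL9 (0.45). Lower ones were those of PBS3 (-3.86), TET15 (-3.53), GLP6 (-3.24), GAT1_2.1 (-2.04), CYP82C2 (-1.93), DAR3 (-1.73), NAC019 (-1.58), RD29A (-1.22), LTI30 (-0.65) and AOC2 (-0.57). TET15, GLP6, DAR3, RD29A and MYB36 lie on chromosome 5 from AT5G25000 onwards, and GLP6 in the stretch where replicate 1 stood apart. With normexp and with the authors' value table GLP6 no longer passed. ACS9 was not well above background in Col-0 with NaCl or in the unstressed quadruple mutant. In unstressed Col-0, PBS3, GLP6, CYP82C2 and RD29A were not well above background, nor were 8 of 12 seed storage genes in either Col-0 group, so these sizes are not exact.

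Probes outside the tested loci also passed limma for the salt response in Col-0. These were 118 of 148 probes of small nucleolar and U RNAs, all lower, and 23 of 41 of microRNAs, 19 of them lower. The array design's other series gave 334 of 836 (named CUFF), 1098 of 3435 (Group), 171 of 570 (OMAT), 108 of 368 (gb), 297 of 731 (chromosome tiles) and 18 of 36 (other names). Probes tiling single loci gave 145 of 191 on the given strand and 63 of 97 on the complementary strand.

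The 9 contrasts of 3 against 3 arrays each allow 10 splits, too few for a share under 0.05. The real count and the highest of the other splits by limma were 13569 and 3 for the salt response in Col-0, 12765 and 0 in hda19 and 13726 and 0 in the quadruple mutant. They were 7813 and 1 for hda19 against Col-0 without NaCl, 7921 and 4 with NaCl, and 4047 and 1 and 6035 and 0 for the quadruple mutant against Col-0. Between the mutants they were 9192 and 1 without and 10381 and 0 with NaCl. Where the highest was 0, up to 1570, 2242, 2949 and 2387 loci had an unadjusted p below 0.05 in another split, in the order given.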

How the results depend on the processing

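Leaving out chromosome 5 was chosen only after the result was seen, and the other alternatives were fixed before. Counts of all called loci in the 9 contrasts of 3 against 3 arrays stayed within 1.5 times under the alternatives fixed before, except 4734 for hda19 against Col-0 with NaCl when only the groups compared were fitted (7921 otherwise) and 6752 for the quadruple mutant without NaCl with array weights (4047 otherwise). Without chromosome 5, where calls were denser, that mutant had 2414 loci without and 4012 with NaCl and 139 in the interaction. With 1 array left out, salt responses gave 11644 to 12994 loci and the other 6 contrasts 2762 to 10204.

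Counts of loci changed at least 2-fold were lower with normexp. They were 1834, 1766 and 1718 for the salt response in Col-0, hda19 and the quadruple mutant (3166, 3013 and 2933 otherwise). Without and with NaCl they were 434 and 498 for hda19 against Col-0 (1232 and 1104), 294 and 459 for the quadruple mutant (734 and 949) and 688 and 842 between the mutants (1674 and 1784). The authors' value table gave 620 and 649, 420 and 606, and 972 and 1121 for these pairs. Without chromosome 5 the quadruple mutant had 324 and 482 such loci and 75 in the interaction. Quantile normalisation, normexp and the authors' value table turned the balance of higher and lower loci for hda19 against Col-0 and between the mutants in both conditions and for the quadruple mutant without NaCl. The causes were not tested.

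The interaction counts moved most. For hda19 (455) they were 219 without the filter on dim probes, 717 with a replicate block, 883 with a slide block, 1245 with array weights and 210 with only the groups compared. With 1 array left out they ranged from 195 (Col-0 non-stress replicate 2) to 961 (hda19 NaCl replicate 2). For the quadruple mutant (277) the counts were 141 without the filter, 446 with a replicate block, 516 with a slide block and 1460 with array weights. With 1 array left out they ranged from 150 (its non-stress replicate 3) to 270. For hda19, 132 of these loci changed at least 2-fold, against 258 with array weights, 80 with only the groups compared, 250 without hda19 NaCl replicate 2, 86 without hda19 non-stress replicate 3 and 77 and 85 without Col-0 non-stress replicates 1 and 2. For the quadruple mutant 134 did, against 355 with array weights, 89 without the filter, 84 without its non-stress replicate 3 and 89 without Col-0 non-stress replicate 1. The causes were not tested.

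Of 242 gene list tests 79 passed. With a correlation estimated from the residuals 11 passed, and with fry, which does not compare a list with other genes, 124 did, 72 of them shared. The similarity of salt responses without the filter, which adds dim loci, was 0.846 for Col-0 and hda19, 0.869 for Col-0 and the quadruple mutant and 0.818 for the mutants (0.923, 0.924 and 0.886 with it). For the overlap of the mutant effects, NaCl, the count was 852 when only the groups compared were fitted, and the cause was not tested. For named genes and single list tests, 19904 values kept direction and side of the threshold. Of the rest, 892 newly passed, 1425 no longer passed, 88 changed sign without and 0 while passing. Of the 79 list tests that passed, 66 still did without members on chromosome 5 and 13 did not.

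Replicate number and slide coincide for the salt response in Col-0 and the quadruple mutant against Col-0, where a replicate block gave 14611, 5206 and 7326 loci. In the other contrasts not every pair correlated above 0.1, although equal numbers mostly share a slide. Outside their group, 17 of 18 arrays correlated best with their own number and 15 with an array of their slide. There the block gave 13827 and 14824 loci for the salt response in hda19 and the quadruple mutant, 9177 and 9364 for hda19 against Col-0 and 10470 and 11687 between the mutants. It ended 5 list calls and added 3, and changed no other list call. Signal over background limits genes dim in a group to a bound.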

Other observations

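The loci in this part were chosen only after the result was seen, but the limma tests were written before. At 5 loci tiled on both strands, complementary probes rose with NaCl in Col-0. Such probes passed in 21 of 21 at RD29A, 13 of 13 at RD29B, 16 of 17 at RD20, 8 of 9 at DREB2A and 3 of 3 at NCED3. Without NaCl only 2, 0, 1, 1 and 0 of them were well above background on all 3 arrays, so their sizes are not given. Given-strand medians there were 5.21, 6.45, 6.16, 5.18 and 4.96. At HSFA3, HSP70, HSP90.1, HSP81-3 and Hsp70-2 no complementary probe was higher by limma (0), with medians of -0.31 (1 probe), 0.17, -0.35, -0.29 and -0.51. Their given-strand medians were 1.29 (HSFA3), 0.37, 0.07, -0.45 and -0.48.

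A run of neighbouring loci on chromosome 4 was low in hda19. Without NaCl AT4G22485, AT4G22505, AT4G22513, AT4G22517 and AT4G22520 were not well above background in hda19 and at least 59.3-, 37.9-, 89.7-, 120- and 22.8-fold lower than in Col-0 (adjusted p by limma 2.62e-09 to 2.05e-06). AT4G22490 between them changed by -2.16 ± 0.25. The tested loci on either side, AT4G22470 (-0.01 ± 0.15) and AT4G22530 (0.01 ± 0.10), did not pass in hda19. With NaCl AT4G22505 and AT4G22520 were at least 39- and 22.9-fold lower in hda19. AT4G22485, AT4G22513 and AT4G22517 changed by -6.86 ± 0.72, -7.69 ± 0.56 and -8.01 ± 0.67, each well above background on 1 of 3 hda19 arrays, and AT4G22490 by -2.44 ± 0.25. In the quadruple mutant without NaCl these 6 loci differed from Col-0 by -0.30 to -0.56 (adjusted p by limma 0.265 to 0.668). With NaCl AT4G22490 (-0.82 ± 0.25), AT4G22505 (-1.38 ± 0.32) and AT4G22520 (-1.12 ± 0.34) were lower in that mutant.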
